A study of Arabidopsis thaliana with 4 samples.

How the data were processed

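Messenger RNA enriched with oligo(dT) beads from roots of 4 seedling samples was sequenced on an Illumina HiSeq 2000 or another sequencer, per the labels' protocols. The submitters' processing notes name the genome build TAIR10; the aligner and the counting program are not given in the sources used here. For each library the authors deposited a table of transcripts with a read count, a coding length, the percent of that length covered by reads and an RPKM value, which scales reads by coding length and library total. Per the file headers, the read counts sum to the stated totals of 13697345 for Col control, 13819365 for Col Al, 13735435 for luh-4 control and 13450338 for luh-4 Al. The deposited RPKM equalled the read count scaled by that total and by the length, with a relative difference of at most 5e-15. Of the lengths, 99.99% were multiples of 3, so they are coding lengths. Transcripts without reads were not listed and were taken as 0 reads.

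Loci with several transcripts appeared to be counted on part of their sequence. In Col control, among loci with at least 100 reads, the percent coverage in the deposited tables was under 90% for 1.2% of 7513 loci with 1 reference transcript and for 28.3% of 3986 loci with several. LUH, LUG and MATE were covered over less than 20% of their length, so their values rest on few reads and may understate their expression. Of 417 loci on the gene lists, 27 were not listed in any library, STOP1, SLK2 and TPL among them, and were not measured here. Genes with near-identical copies, such as the LHCB1 and RBCS genes, XTH12 and XTH13, or CYP71A12 and CYP71A13, can share reads and are uncertain as single genes. Strand was not stated, so reads of overlapping antisense genes cannot be separated.

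Reads and RPKM were summed over the listed transcripts of each of 21531 loci. Symbols came from the gene lists and from a TAIR10.1 gene table, in which 21258 loci matched; it also gave which genes neighbour each other and on which chromosome they lie, and no coordinates are printed. Groups followed the genotype and treatment labels. With 1 library per group no test was run on a single comparison. A gene was measured where its RPKM was at least 1 in a library compared, and its log2 ratio was taken on RPKM plus a pseudocount of 0.1, which understates changes of low genes. It passed the size rule at a log2 ratio of at least 1 or at most -1 with a 95% interval that excluded 0. Intervals were exact conditional binomial (Clopper-Pearson) intervals on the reads, without the pseudocount. For the difference between Al responses they were normal approximations on log reads with 0.5 added. PCR reads are not independent molecules, so intervals cover counting error only. A count of 0 allows up to 3 reads. A fold given as at least some value takes those 3 reads and the other library's count as it stands, without its counting error. The 3 reads are 0.217 to 0.223 RPKM for a coding length of 1 kb in these libraries.

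The comparisons, the size rule, the 26 gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Named were, per comparison, the 8 genes with a symbol and an RPKM of at least 5 that were furthest up and the 8 furthest down, up to 4 members of each list outside the central 95% of random medians or with at least 3 members past the size rule, and LUH, ALMT1, MATE, ALS3, STOP1 and PME46. Other genes named in the closing section, and LUG, SLK1 and the members past the size rule of lists within the random range, were chosen after their values were seen. Each list's median was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. Setting members with 0 reads to 3 reads left the medians of the 26 lists as printed, except for LUH and its partners in the difference between Al responses (0.05, then 0.07). The alternatives fixed in advance were a pseudocount of 1 or 0.01, an RPKM minimum of 5 or none, centring on the median gene, TMM scaling of the reads (edgeR 4.0.16 in R 4.3.3) and no counting interval. Alternatives chosen after seeing the data took transcripts one by one, kept loci with at least 50% coverage, left out photosynthesis genes, used Col control as the baseline of luh-4 Al, or fitted genotype plus treatment to the reads of 17435 loci over the 4 libraries (edgeR quasi-likelihood test, TMM factors, Benjamini-Hochberg adjustment). That fit has 1 residual degree of freedom, and none without any 1 library, and its spread is the departure of the libraries from additive effects, not variation between plants.

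The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The size rule was tested on simulated reads for 16734 genes with 200 changed. For the Al response of Col it recovered 91.0% of 2.5-fold and 98.0% of 4-fold changes and called 0.25% of unchanged genes, and 95.7% of intervals held the true ratio. For the difference between Al responses these were 86.0%, 96.0%, 0.73% and 94.9%. For Al over both genotypes, the fit of genotype plus treatment recovered 85% of 2.5-fold and 97% of 4-fold changes and called 0.0406% of unchanged genes, of 17435. The simulated reads hold counting error, and for that fit the spread it estimated, but no variation between plants.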

Results

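Polyadenylated RNA was measured by sequencing in roots of Arabidopsis thaliana seedlings of the Columbia (Col) wild type and of luh-4, a mutant of LEUNIG_HOMOLOG (LUH), which encodes a transcriptional co-repressor. Seedlings 6 d old, about 500 per treatment and grown at pH 5.5, were placed in nutrient solution at pH 4.2 with 0 or 25 µM AlCl3. There were 4 groups, named here Col control, Col Al, luh-4 control and luh-4 Al, with 1 library each. The treatment description has roots of both arms collected after 4 h, while the controls carry a time point of 0 h, so the Al ratios may also hold a response to 4 h in solution at pH 4.2. Libraries held 13.45 to 13.82 M reads assigned to transcripts, and between 20077 and 20284 loci were listed in each. Log2 expression across 11918 genes correlated at 0.989 between the genotypes under the same treatment and at 0.969 to 0.977 between control and Al libraries. These genes had an RPKM of at least 5 in all 4 libraries. There were no replicates, so no difference below has a replicate check and no p-value is given for a single comparison. Values are log2 ratios of RPKM with 95% intervals in parentheses that cover counting error only, and each comparison is of libraries, not of conditions. A gene rose or fell, or was higher or lower, where it passed the size rule of at least a 2-fold difference with an interval that excludes 0. Genes given as furthest up or down in a comparison are those past the rule with a symbol and an RPKM of at least 5 in a library compared. Gene list medians are set against the medians of 10000 random lists of matched expression, as a description of these libraries.

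LUH (AT2G32700), the gene mutated in luh-4, had 75 reads in Col control, 63 in Col Al and 0 in both luh-4 libraries. It was at least 25.1-fold lower in luh-4 without Al and at least 20.4-fold lower with Al, taking 3 reads in the luh-4 library as the limit that a count of 0 allows. The upper ends of its intervals were -4.31 and -4.01. These reads came from 1 listed transcript covered over at most 18.96% of its coding length. In Col the LUH ratio of Al to control was -0.25 (-0.77 to 0.24). Of the related co-repressors and partners on the same list, LUG had an Al ratio of 0.27 (-0.15 to 0.70) in Col and 0.65 (0.25 to 1.1) in luh-4, and SLK1 had 0.07 (-0.07 to 0.21) and -0.07 (-0.21 to 0.06). LUG too was covered over only a short part of its coding length, at most 15.74%. The medians of this list lay within the random range in every comparison, from -0.06 to 0.17.

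The first comparison asked how Col roots responded to Al. After Al, 444 genes rose and 496 fell of 17068 measured, 129 and 101 of them by at least 4-fold. The AAA-ATPase gene AATP1 rose from 41 to 2319 reads, a log2 ratio of 5.74 (5.36 to 6.29). The cytochrome P450 gene CYP71A12, of indole phytoalexin synthesis, rose by 4.84 (4.57 to 5.18), BGLU25, a probable inactive beta-glucosidase, by 4.28 (4.18 to 4.39) and the prenylated rab acceptor gene PRA1.B5 by 3.77 (3.57 to 4.00). The zinc finger gene ZAT7 went from 1 to 62 reads (5.20, 3.41 to 11.27), and the calcium-binding protein gene CML37 (4.23), the late embryogenesis abundant gene LEA4-5 (3.85) and the transcription factor gene NAC042 (3.80) also rose. Among the genes furthest down, AGD11, described in the deposited annotation as a calmodulin-like protein, went from 39 reads to 0, at least 13.1-fold lower. The remaining 7 were CID5 at -4.53 (-7.11 to -3.21), S8H, the scopoletin 8-hydroxylase of iron-mobilising coumarins, at -4.42 (-5.37 to -3.83), UCC3 at -3.73, the glutathione transferase GSTU14 at -3.44, the arabinogalactan protein gene AGP41 at -3.32, the root hair gene RHS8 at -2.77 and XTH13 at -2.61.

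Genes of Al resistance had a median of 0.35 in Col, at percentile 99.98 of random lists, although 1 of 15 measured members passed the size rule. That member was MATE (AT1G51340), a citrate transporter, at 1.04 (0.58 to 1.57). The malate channel gene ALMT1 (AT1G08430) went from 5152 to 9034 reads, a ratio of 0.80 (0.75 to 0.85), ALS3 (AT2G37330), an ABC transporter gene, had 0.63 (0.43 to 0.83) and the F-box gene RAE1 (AT5G01720) 0.70 (0.59 to 0.81). Glutathione transferase and oxidative stress genes had a median of 0.62, above the random range, with 6 of 21 rising, among them GSTU12 at 2.70 (2.28 to 3.19), the kinase gene OXI1 at 1.76 (1.59 to 1.93) and GSTF7 at 1.56 (1.48 to 1.63). Of 22 early wound, touch and elicitor genes, 8 rose and 0 fell (median 0.63), including NHL10 at 2.87 (2.56 to 3.22) and ZAT12 at 2.80 (2.45 to 3.19). Jasmonate genes had a median of 0.36 with 3 of 13 rising: JAZ10 at 2.3 (1.08 to 4.2), LOX4 at 1.55 (1.09 to 2.24) and JAZ7 at 1.28 (0.02 to 2.85). Ethylene genes had 0.20 with 2 of 17 rising, ACS7 at 1.60 (0.93 to 2.52) and ERF1 at 1.03 (0.20 to 1.99).

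Root hair markers in Col had a median of -0.86, below the random range of -0.15 to 0.18, and 4 of 12 fell: the expansin EXPA7 at -2.03 (-2.18 to -1.87), MRH6 at -1.94 (-2.47 to -1.47), COBL9 at -1.64 (-1.81 to -1.49) and the transcription factor RSL4 at -1.25 (-2.04 to -0.58). Xyloglucan endotransglucosylase/hydrolases, which remodel wall xyloglucan, had -0.52, with 5 of 19 falling, XTH33 at -3.06 (-4.81 to -2.10) furthest, and 2 rising, XTH22 at 1.79 (1.68 to 1.90) among them. Of 20 pectin methylesterases 2 fell (median -0.13): PME46 (AT5G04960) at -1.66 (-1.77 to -1.55) and PME17 at -1.18 (-1.25 to -1.12). PME46 was named in advance because published work on this mutant discusses it, so it may have been chosen on these samples. Alpha-expansins had -0.32, with EXPA2 falling from 21 reads to 0 (at least 7.06-fold) besides EXPA7. The xylosidase gene BXL1, 1 of 3 LUH-dependent mucilage genes, fell by 1.66 (-1.88 to -1.47). Heat shock genes had -0.37 with 3 of 10 falling, HSP17.6A at -1.92 (-2.25 to -1.61) first, and phosphate starvation genes -0.25 with 0 of 18 past the rule. In the iron deficiency list (median -0.09), S8H, MYB72 at -1.86 (-2.96 to -1.05) and the ferric reductase FRO2 at -1.54 (-1.59 to -1.49) fell and 20 of 23 did not pass. Green shoot markers had a median of -0.62, with 0 of 15 past the rule. With a pseudocount of 1 RPKM the ratios of MATE (0.83), ERF1 (0.78) and JAZ7 (0.87) no longer passed, nor did RSL4 and CBP60G, JAZ7 did not pass under TMM scaling (1.26) either, and with an RPKM minimum of 5 the counts were 274 and 312 and the heat shock median was -0.21.

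The remaining lists had medians within the random range in Col. These were 0.24 for salicylate defence, where WRKY70 rose by 2.60 (1.97 to 3.45), 0.11 for abscisate and osmotic stress, -0.09 for auxin, -0.21 for flavonoid synthesis, -0.07 for both lignin synthesis and the pectin methylesterase inhibitors, 0.06 for meristem and cell division markers, -0.04 for endodermis and xylem markers and -0.05 for reference genes. Members of these lists past the rule, besides WRKY70, were PMEI8 at -2.22 (-3.75 to -1.14) and PMEI4 at -1.47 (-1.72 to -1.22) of 8 inhibitors, GH3.1 of the auxin list at 1.16 (0.98 to 1.37), F3PH of flavonoid synthesis at -1.03 (-1.31 to -0.77), and HAI1 at 1.32 (0.63 to 2.21) and NCED3 at 1.13 (0.62 to 1.77) of the abscisate list. F3PH (-0.95), HAI1 (0.91) and NCED3 (0.82) no longer passed with a pseudocount of 1 RPKM. Clock genes had -0.09 for the morning list (2 measured) and 0.26 for the evening list (6 measured), with none past the size rule.

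The second comparison asked the same of luh-4 roots, where 345 genes rose and 531 fell of 17117 measured. AATP1 at 5.58 (5.21 to 6.11), CYP71A12 at 4.66 (4.37 to 5.05), LEA4-5 at 3.90, BGLU25 at 3.75, the protease inhibitor gene CYSA at 3.74, NAC042 at 3.65, the glutathione transferase GSTU22 at 3.35 and PRA1.B5 at 3.33 were furthest up. Furthest down were S8H at -5.11 (-7.95 to -4.09), the germin-like gene GER3 at -4.18 (-6.35 to -3.04) and the light-harvesting protein genes LHCB1.2 (-4.0), LHCB2.1 (-3.72), LHCB1.1 (-3.70) and LHCB2.2 (-3.20), near-identical copies whose single values are uncertain. CYP705A5, a cytochrome P450 of thalianol metabolism, fell by 3.48 (-3.87 to -3.18) and the annexin gene ANNAT4 by 3.02. Al resistance genes had a median of 0.39, above the random range, with MATE rising by 1.53 (1.04 to 2.14). ALMT1 had 0.81 (0.77 to 0.86), RAE1 0.78 (0.68 to 0.90) and ALS3 0.42 (0.23 to 0.61). Of 21 glutathione transferase and oxidative stress genes 7 rose (median 0.41), GSTU12 by 2.14 (1.68 to 2.68) and GSTF7 by 1.47 (1.39 to 1.55).

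Jasmonate genes in luh-4 had a median of -1.08, with 8 of 16 falling and 0 rising. The transaminase gene TAT3 fell by 3.1 (-4.62 to -2.32), the lipoxygenase gene LOX3 by 2.79 (-4.91 to -2.21) and the repressor gene JAZ8 by 2.74 (-4.37 to -1.61). Green shoot markers moved with them, at a median of -1.98 and with 12 of 15 falling. Of 23 wound, touch and elicitor genes 4 rose, NHL10 by 2.15 (1.86 to 2.48) and ZAT12 by 2.02 (1.69 to 2.38) among them, and 5 fell, ERF109 by 2.63 (-3.64 to -1.90) first (median -0.15). Ethylene genes had -0.19, with ERF105 at -1.11 (-1.46 to -0.78) and ERF104 at -1.07 (-1.32 to -0.84) falling. When luh-4 Al was set against Col control in place of luh-4 control, the medians were 0.21 for jasmonate, 0.08 for ethylene and 0.30 for wound genes, opposite in sign, while the shoot marker median was -0.27 and the root hair median -0.06. Of the 876 calls, 439 were kept with that baseline.

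Root hair markers in luh-4 had a median of -0.27 with 0 of 12 past the size rule, EXPA7 at -0.85 (-0.96 to -0.75), COBL9 at -0.85 (-0.98 to -0.73) and MRH6 at -0.59 (-0.95 to -0.23). PME46 had -0.68 (-0.76 to -0.60), and 0 of 20 pectin methylesterases passed (median 0.00). Their inhibitors had a median of 0.02, with PMEI8 falling by 2.44 (-5.1 to -0.95) as 1 of 7. Among the xyloglucan genes (median -0.34) XTH13 at -2.12 (-2.58 to -1.73), XTH33 at -2.01 (-2.91 to -1.33) and XTH12 at -1.09 (-1.31 to -0.87) fell and XTH22 rose by 1.72 (1.63 to 1.83). Alpha-expansins had 0.13, with EXPA1 at 1.61 (0.17 to 3.9) and EXPA12 at 1.9 (0.65 to 3.86) rising, and the mucilage genes -0.28, with BXL1 at -2.39 (-2.70 to -2.15). Heat shock genes had -0.57, with 4 of 11 falling, HSP17.6A by 2.33 (-2.85 to -1.88), and phosphate starvation genes -0.24, with RNS1 falling by 1.34 (-1.70 to -1.01). FRO2 fell by 1.49 (-1.54 to -1.43) and MYB72 by 1.92 (-3.13 to -1.06) in the iron list (median -0.11). Medians within the random range were -0.14 for auxin, -0.06 for salicylate defence, -0.07 for lignin synthesis, 0.12 for flavonoid synthesis, 0.14 for abscisate, 0.07 and 0.22 for the clock lists, 0.01 for meristem, -0.06 for endodermis and xylem and -0.11 for reference genes. In these lists the auxin genes IAA20 (1.43) and IAA30 (1.16) and WRKY70 (1.14) rose, and GRX480 (-1.15), KIN2 of the abscisate list (-1.14) and CASP5 (-1.39) fell. With a pseudocount of 1 RPKM 316 genes fell and HSFA2 (-0.70), HSP23.6 (-0.90), WRKY18 (-0.91), EXPA1 (0.78), IAA20 (0.89) and IAA30 (0.85) no longer passed, which leaves 2 of the 4 heat shock genes, and with an RPKM minimum of 5 the counts were 203 and 274 and the jasmonate median -0.67.

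The Al responses of the genotypes overlapped. Of 16750 genes measured in both, 200 rose in both, where independent lists of 414 and 319 genes would share 7.88, and 180 fell in both, where lists of 466 and 452 would share 12.6. The 2 responses share no library. Across the 11918 genes with an RPKM of at least 5 in all 4 libraries, which are not independent replicates, they correlated with Pearson r of 0.684 and Spearman rho of 0.522. There were 10 genes past the size rule in opposite directions, 8 of which rose in Col and fell in luh-4. A fit of genotype plus treatment over the 4 libraries (edgeR quasi-likelihood test, 1 residual degree of freedom) takes any difference in Al response between the genotypes as error. At a Benjamini-Hochberg adjusted p of 0.05 it called 958 genes higher and 1114 lower with Al, of 17435, including 191 of the 200 and 169 of the 180. Those 200 and 180 were picked on the same reads, so their calls in this fit are no independent check.

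**Figure D1:**
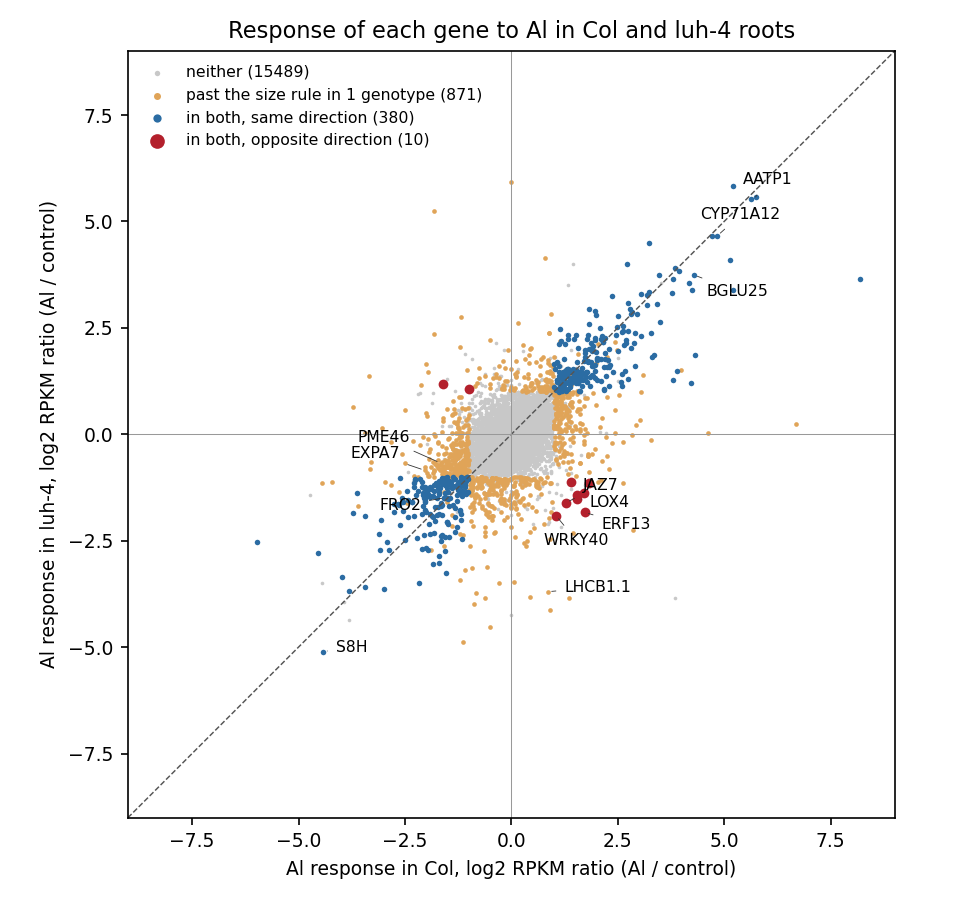
Log2 RPKM ratio of Al to control for each of 16750 genes in Col (x axis) and luh-4 (y axis), with the dashed line marking equal responses. Blue points are the genes past the size rule in both genotypes in the same direction, red the 10 in opposite directions and orange those past it in 1 genotype.

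The third comparison asked how luh-4 differed from Col without Al. In luh-4 control, 265 genes were higher and 146 lower of 17070 measured. Furthest up were GER3 at 4.2 (3.06 to 6.38), LHCB1.1 at 3.88 (3.25 to 4.80), LHCB1.2 at 3.47 (2.90 to 4.26), and the Rubisco small subunit genes RBCS2B at 3.57 (2.80 to 4.63), RBCS1A at 2.87 (2.59 to 3.18) and RBCS3B at 2.81 (2.22 to 3.53), with the ethylene response factor genes ERF109 at 3.09 (2.29 to 4.34) and ERF13 at 2.97 (2.33 to 3.83). Green shoot markers as a list had a median of 2.03, with 10 of 15 higher and 0 lower. Beside them, jasmonate genes had a median of 1.46, above the random range, with 10 of 16 higher: TAT3 at 2.98 (2.23 to 4.40), JAZ7 at 2.67 (1.62 to 4.16), LOX4 at 2.46 (2.07 to 3.15) and LOX3 at 2.42 (1.84 to 4.04) were furthest. Of 22 wound, touch and elicitor genes 7 were higher (median 0.53), WRKY40 at 2.32 (1.96 to 2.74) among them. Ethylene genes had 0.35, with 3 of 17 higher, ERF105 at 1.34 (0.99 to 1.71) first, and salicylate genes 0.36, with GRX480 at 1.87 (1.05 to 2.88) and WRKY70 at 1.71 (1.01 to 2.59) higher of 10.

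Lower in luh-4 without Al were QQS, which went from 23 reads in Col to 0 (at least 7.69-fold), and MRD1, with 190 reads in Col and 2 in luh-4 (-6.09, -9.63 to -4.70). RTFL17 (-2.48), the signalling peptide gene CLE2 (-1.87), the calcium sensor gene CBL8 at -1.64 (-2.14 to -1.20), the glucosyltransferase gene UGT74E2 at -1.38 (-1.81 to -1.01), the molybdate transporter gene MOT1 at -1.30 (-1.70 to -0.94) and S8H at -1.25 (-1.54 to -0.98) followed. Several lists had medians outside the random range with few members past the rule: flavonoid synthesis -0.36 (0 of 7), endodermis and xylem -0.22 (CASP5 higher at 1.32, 0.73 to 1.99), iron deficiency -0.19 (BHLH101 higher at 2.07, 0.74 to 4.33), heat shock -0.19 (0 of 11), lignin -0.12 (0 of 18), glutathione transferases -0.10 (0 of 21, with a counting interval of -0.16 to 0.02), root hair 0.22 (0 of 12), xyloglucan genes 0.15 (0 of 19) and meristem 0.15 (0 of 16). Within the range were Al resistance (0.01), where WRKY46 was higher at 1.63 (0.82 to 2.69), pectin methylesterases (-0.03) and their inhibitors (-0.05), mucilage (-0.09), expansins (0.01), auxin (0.05), phosphate (0.05), abscisate (0.12), the clock lists (-0.21 and -0.02) and reference genes (0.02), although UBQ10 was higher at 1.04 (0.69 to 1.33). Of these lists EXPA2 was also lower at -3.43 (-9.77 to -1.76), and IAA29 at 1.75 (0.36 to 4.04) and RNS1 at 1.54 (1.19 to 1.91) were higher. PME46 had 0.31 (0.24 to 0.38), ALMT1 0.15 (0.09 to 0.20), ALS3 0.21 (0.00 to 0.42) and MATE -0.43 (-1.08 to 0.18). With a pseudocount of 1 RPKM the counts were 140 and 56 and ERF1 (0.97), IAA29 (0.87) and UBQ10 (0.97) no longer passed, and with an RPKM minimum of 5 they were 94 and 45, the jasmonate median 0.98 and the wound median 0.31.

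**Figure D2:**
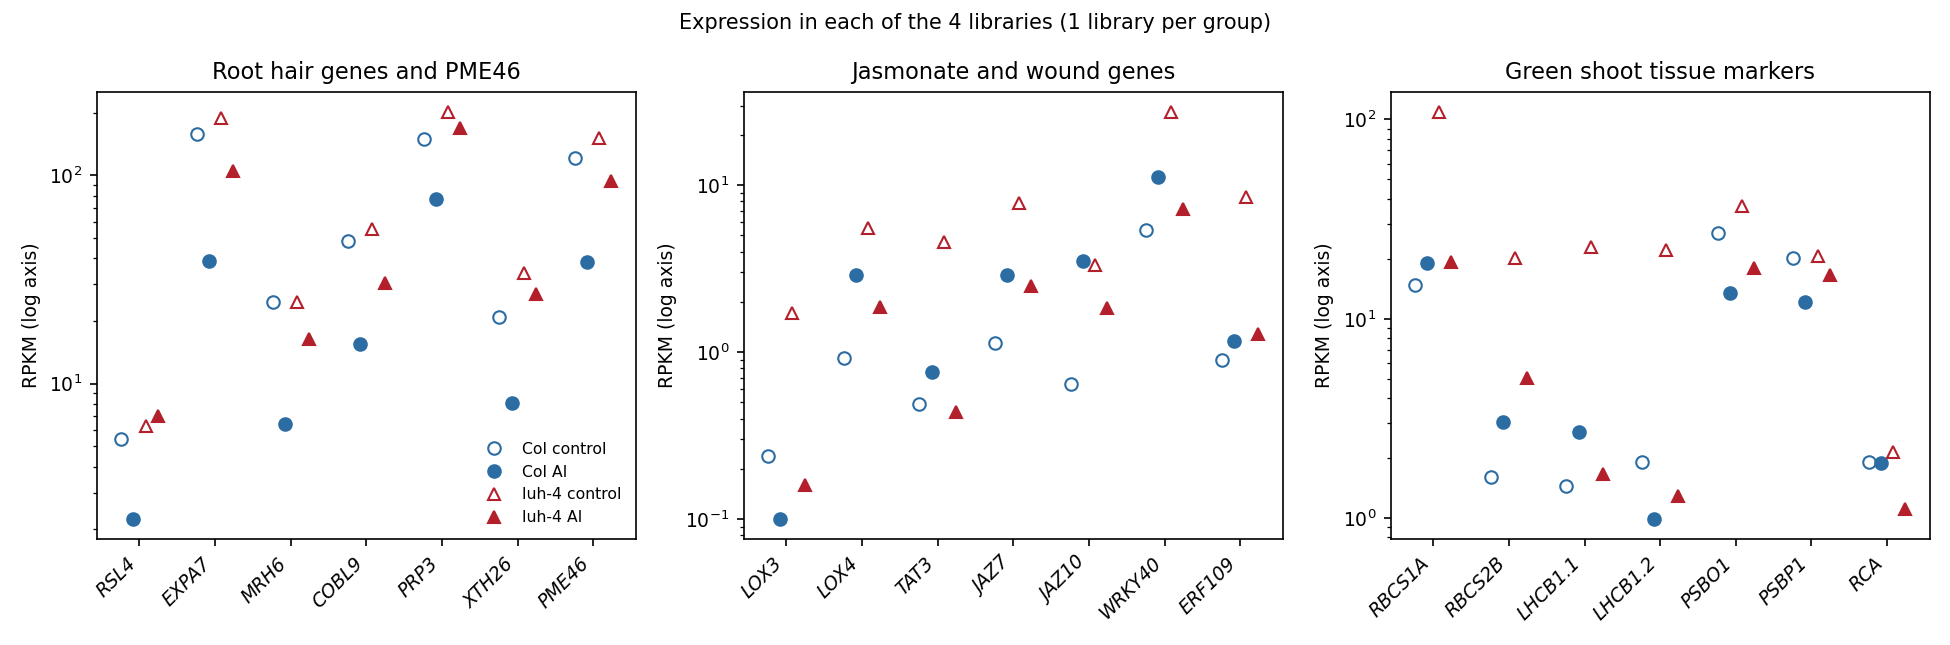
RPKM (log axis) in each of the 4 libraries, 1 point per gene and library, for root hair genes and PME46 (left), jasmonate and wound genes (middle) and green shoot markers (right), genes picked after their values were seen. Circles are Col and triangles luh-4, open without Al and filled with Al; the open triangle lies furthest up for TAT3, LOX4 and RBCS1A, and the filled circle lowest for EXPA7 and PME46.

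The fourth comparison asked how the genotypes differed under Al. In luh-4 Al, 208 genes were higher and 161 lower than in Col Al, of 17011. Furthest up were AGP41 at 2.44 (0.75 to 4.95), the glutathione transferase gene GSTU14 at 1.98 (1.57 to 2.45), XTH26 at 1.72 (1.41 to 2.08), RSL4 at 1.60 (0.96 to 2.37), the root hair peroxidase gene RHS18 at 1.46 (1.16 to 1.80) and EXPA7 at 1.43 (1.27 to 1.60), with the peptide gene RGF5 at 2.19 (0.70 to 4.3) and the esterase gene MES13 at 1.92 (1.38 to 2.64). Root hair markers had a median of 0.98, above the random range of -0.16 to 0.10, with 5 of 12 higher and 12 of 12 above 0, MRH6 at 1.35 (0.84 to 1.90) and PRP3 at 1.13 (1.02 to 1.24) among them. PME46 was higher at 1.29 (1.18 to 1.40), from 903 reads in Col Al to 2146, and was the single pectin methylesterase of 20 past the rule (median 0.14). Expansins had 0.50 (2 of 12 higher), xyloglucan genes 0.26 (4 of 19 higher) and pectin methylesterase inhibitors 0.30 (0 of 6). EXPA7 and EXPA18 stand on both the root hair and the expansin list.

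Lower in luh-4 under Al were QQS (22 reads to 0, at least 7.14-fold), MRD1 at -5.71 (-8.33 to -4.47), the peptide gene CLE6 at -1.52, UGT74E2 at -1.43 (-1.73 to -1.15), GSTU11 at -1.42 (-2.02 to -0.89), At17.1 at -1.28, HSP17.6A at -1.22 (-1.77 to -0.71) and PAR1 at -1.16 (-2.16 to -0.27). Jasmonate genes had a median of -0.22 (0 of 13 past the rule) and wound genes -0.32 (0 of 22), both below the random range, as were glutathione transferases at -0.24, heat shock genes at -0.36 and iron genes at -0.20. Green shoot markers had 0.34, with GAPA higher at 1.05 (0.31 to 1.96), phosphate genes 0.14 and meristem markers 0.11, above it. ALMT1 had 0.17 (0.12 to 0.21), MATE 0.06 (-0.32 to 0.45) and ALS3 0.00 (-0.17 to 0.18), and Al resistance genes a median of 0.05. Other medians within the range were 0.00 for mucilage, 0.06 for auxin, -0.05 for ethylene, -0.03 for salicylate, -0.07 for lignin, 0.13 for flavonoids, -0.08 for abscisate, -0.04 and -0.03 for the clock lists, -0.13 for endodermis and xylem and 0.06 for reference genes. In these lists IAA29 was higher at 1.69 (0.40 to 3.67), and the ethylene synthesis gene ACS7 at -1.01 (-1.75 to -0.40) and NCED3 at -1.04 (-1.66 to -0.53) were lower. ACS7 did not pass with centring or TMM scaling (-0.99 in each). With a pseudocount of 1 RPKM the counts were 100 and 67 and XTH33, XTH13, S8H, GAPA, PAR1, IAA29, ACS7 and NCED3 no longer passed, and without the RPKM minimum the inhibitor median was 0.03. Counts were 90 and 41 with an RPKM minimum of 5, and 308 and 276 without the counting interval.

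Of 16646 genes measured in both genotype comparisons, 13 were higher in luh-4 in both (2.26 for independent lists) and 20 lower in both (1.04), while 11 passed the rule in opposite directions. UGT74E2, CBL8, S8H, QQS, MRD1 and AT4G29200 were among the 20, as was LUH, the mutated gene itself. The fit of genotype plus treatment (edgeR, adjusted p of 0.05) called 59 genes higher and 100 lower in luh-4. Across the 11918 genes with an RPKM of at least 5 in all 4 libraries, the genotype differences without and with Al had a Pearson r of 0.246 and a Spearman rho of 0.226. That filter leaves out LUH, QQS, MRD1 and AT4G29200.

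The fifth comparison asked whether the Al response differed between the genotypes, as the luh-4 log2 ratio minus that of Col. It was more positive in luh-4 for 235 genes and more negative for 394, of 17435. Root hair markers had a median difference of 0.62, above the random range, with 3 of 12 past the rule: RSL4 at 1.40 (0.59 to 2.25), MRH6 at 1.35 (0.77 to 1.94) and EXPA7 at 1.17 (0.99 to 1.36). The PME46 difference of 0.98 (0.85 to 1.11) did not reach the size rule, and pectin methylesterases had a median of 0.17 with 0 of 20 past it. Expansins had 0.33, flavonoid genes 0.40 and xyloglucan genes 0.23, with XTH26 at 1.02 (0.63 to 1.42), while the inhibitor median of 0.30 had a counting interval that includes 0 (-0.04 to 0.59) and 0 of 8 passed. Furthest up were AGP41 at 2.49 (0.61 to 4.21), APG12B at 1.94 (1.13 to 2.75), UCC3 at 1.87, MIF3 at 1.83, the phytochrome substrate gene PKS1 at 1.83 (1.06 to 2.71), CID5 at 1.75, GSTU14 at 1.53 (1.1 to 1.99) and REV7 at 1.48.

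Furthest down were GER3 at -4.67 (-7.01 to -2.59), LHCB1.1 at -4.55 (-5.71 to -3.51), ERF13 at -3.55 (-4.49 to -2.69), CYP705A5 at -3.20 (-3.67 to -2.79), LHCB1.2 at -3.12, LOX4 at -3.06 (-3.86 to -2.52), CML37 at -3.03 and ERF109 at -2.96. Jasmonate genes had a median difference of -1.35 with 12 of 16 past the rule, TAT3 at -3.64 (-5.44 to -2.32) and JAZ10 at -3.12 (-4.86 to -1.65) included. Wound genes had -0.77 (9 of 23), ethylene genes -0.33 (4 of 17) with ERF105 at -1.91 (-2.41 to -1.42), abscisate genes -0.32 with the phosphatase gene HAI1 at -1.15 (-2.24 to -0.15), and green shoot markers -1.74 (9 of 15). Glutathione transferases had -0.13 (0 of 21). The differences of ALMT1 at 0.02 (-0.05 to 0.09), MATE at 0.49 (-0.20 to 1.21) and ALS3 at -0.21 (-0.48 to 0.06) did not pass, and Al resistance genes had a median of 0.01, with 1 of 15 past the rule, WRKY46 at -1.64 (-2.82 to -0.56). Within the random range were mucilage (0.09), auxin (-0.07), salicylate (-0.35), iron (-0.06), phosphate (0.08), lignin (0.01), heat shock (-0.06), the clock lists (0.17 and -0.04), meristem (-0.02), endodermis and xylem (0.01) and reference genes (-0.04). Of these lists IAA20 passed at 1.79 (0.09 to 3.58), GRX480 at -2.06 (-3.22 to -0.91), WRKY70 at -1.45 (-2.3 to -0.68) and RNS1 at -1.1 (-1.66 to -0.55). With a pseudocount of 1 RPKM the counts were 128 and 236 and CID5, XTH26, ERF1 and HAI1 no longer passed. With an RPKM minimum of 5 the counts were 105 and 177 and the abscisate median -0.06, and without the counting interval they were 492 and 688.

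**Figure D3:**
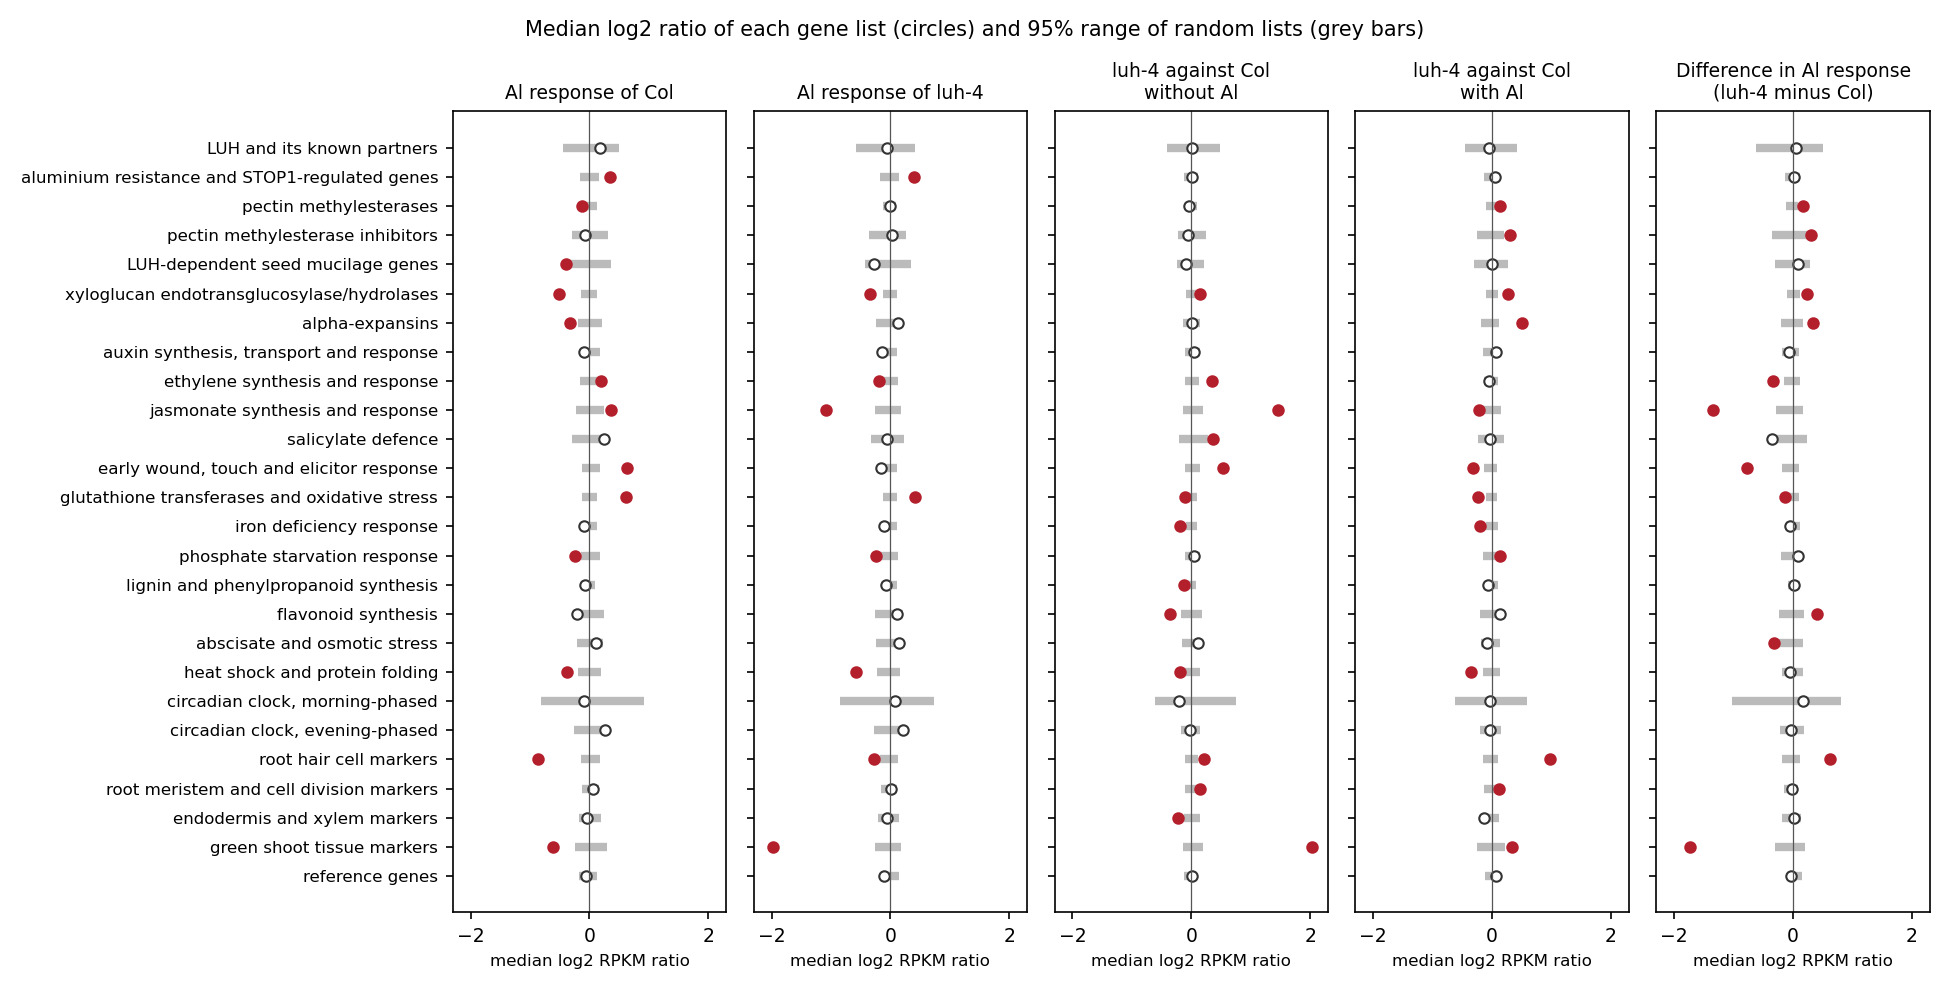
Median log2 RPKM ratio of each of 26 gene lists in the 5 comparisons, with grey bars for the central 95% of medians of 10000 random lists. Filled circles lie outside that range; root hair markers sit at -0.86 in the Al response of Col and at 0.98 in luh-4 against Col with Al, and jasmonate genes at 1.46 in luh-4 against Col without Al.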

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

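All tests in this part were chosen after the results were seen. Results are listed because a list median outside the random range, or a gene past the size rule, in both genotypes had opposite signs in their Al responses; with 1 library per group the difference was not tested. By list median these were jasmonate (0.36 in Col, with 3 of 13 rising, -1.08 in luh-4, with 8 of 16 falling, median difference -1.35) and ethylene (0.20, -0.19, -0.33). For ethylene 2 of 17 rose in Col and 2 other genes of 17 fell in luh-4, so no member passed the rule in opposite directions. With Col control as baseline of luh-4 Al these medians were 0.21 and 0.08, so the opposite direction depends on which control library is used. That baseline adds the genotype difference without Al to the luh-4 response. It therefore cannot tell an unusual luh-4 control library from a higher level in luh-4 that Al lowers. By gene, 8 rose in Col and fell in luh-4, with differences of -3.55 for ERF13, -3.09 for AT3G60700, -3.06 for LOX4, -2.97 for AT4G28930, -2.96 for the cold response factor gene CBF2, -2.96 for WRKY40, -2.89 for JAZ7 and -2.53 for AT1G24600. For 7 of the 8, all but AT4G28930, luh-4 Al stood above Col control. The 8 were picked for rising from Col control, which favours a low value there, so this is no independent check. AT1G55152 and AT1G78922 fell in Col and rose in luh-4, with differences of 2.06 and 2.80, and their luh-4 Al values over Col control were 0.5 and -0.05. Several rest on few reads, such as AT3G60700 with 3 in Col control and 12 in Col Al, and JAZ7 no longer passed in Col with TMM scaling (1.26) or a pseudocount of 1 (0.87).

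Jasmonate genes were high in the luh-4 control library, at a median of 1.46 over Col control, as were 7 of 22 wound genes (median 0.53), which the tests below leave out. This library also had 8279 mitochondrial reads against 13482 to 18120 in the others. Its plastid reads, at 31330, lay within the range of 27730 to 32093 in the others. Library scaling is argued against, since the median gene differed by 0.013. An effect of luh-4 present with and without Al is argued against as well, since with Al the jasmonate median was -0.22, below the random range of -0.20 to 0.15. Green shoot tissue in the luh-4 control sample stays open: shoot markers, 15 of them also measured in Col roots, stood at 2.03 in the same comparison, RBCS1A at 810 reads against 110, while PSBP1 (224 against 219) and RCA (42 against 37) gained few, and no shoot library was analysed here to set what each would need. An effect of luh-4 that appears only without Al, or a difference in how this 1 sample was handled, may also account for it and neither was tested.

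Root hair genes were lowered less by Al in luh-4, with a median difference of 0.62 between the Al responses. Library scaling is argued against by a median gene of -0.022 in luh-4 over Col under Al, and the luh-4 control library alone as the source by a root hair median of 0.98 in that comparison, which leaves that library out. More root hair cells in luh-4 roots, which would raise the markers as much without Al, is argued against as the whole cause by 0.22 (0.16 to 0.29) without Al. Weaker Al exposure of the luh-4 Al sample stays open. The median difference of the Al resistance genes was 0.01, where an equally weakened response would need -0.24. Resampling members gave -0.17 to 0.09, but these are genes of the same 4 libraries, not replicates. Members spread from -1.64 for WRKY46 to 0.49, and their SD of 0.48 is wider than the distance from 0.01 to -0.24. The Al ratios may also hold a response to time in the acidic solution, so this list need not follow Al dose alone. ALS3 had -0.21 and ALMT1 0.02 (-0.05 to 0.09), and glutathione transferases had a median difference of -0.13. A weaker response of root hair genes to Al in luh-4 restates the pattern and was not tested beyond these 4 libraries. With 1 library per group, a difference in how either Al sample was taken or handled cannot be told apart from it.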

How the results depend on the processing

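The alternatives with Col control as baseline, transcripts one by one, at least 50% coverage, without photosynthesis genes and the fit of genotype plus treatment were chosen after the data were seen; the others were fixed in advance. Of 106 recomputed counts 81 stayed within 1.5 times, and of 395 list medians 375 stayed within counting error, 17 moved and 3 reversed. Gene ratios were recomputed only with the other pseudocounts, centring and TMM scaling. Of these 1420 ratios 1389 stayed and none reversed, and the 31 that moved did so with a pseudocount of 1. Calls lost numbered 32, 29 of them with a pseudocount of 1. Col control as baseline was not part of that count. That baseline turned the luh-4 sign for 7 of the 8 genes that rose in Col and fell in luh-4. These genes were picked for rising from Col control, which favours a low value there, so the turned sign is no independent check. With an RPKM minimum of 5, which tests fewer genes, counts higher and lower were 274 and 312 for Al in Col, 203 and 274 for Al in luh-4, 94 and 45 for genotype without Al, 90 and 41 with Al, and 105 and 177 for the difference; list medians were -0.67 for jasmonate in Al in luh-4, 0.98 for jasmonate and 0.31 for wound in genotype without Al, -0.06 for abscisate in the difference and -0.21 for heat shock in Al in Col. With a pseudocount of 1 RPKM the counts were 316 lower for Al in luh-4, 140 and 56 for genotype without Al, 100 and 67 with Al, and 128 and 236 for the difference, and the jasmonate median without Al was 0.96. Without the counting interval they were 220 lower without Al, 276 lower with Al, and 492 and 688 for the difference. Without an RPKM minimum the medians were 0.03 for the inhibitors with Al, 0.32 for wound without Al and -0.52 for heat shock in Al in Col. Centring and TMM gave 0.33 and 0.32 for Al resistance in Col, and TMM -0.14 for lignin without Al. With Col control as baseline the luh-4 Al medians reversed to 0.08 for ethylene, 0.21 for jasmonate and 0.30 for wound, and moved to 0.48 for Al resistance, -0.31 for iron, -0.80 for heat shock, -0.06 for root hair and -0.27 for green shoot genes. Beyond the fewer genes tested, the cause was not tested. Genes past the size rule in both genotypes or both treatments, 200 higher and 180 lower with Al and 13 and 20 in luh-4, were 958, 1114, 59 and 100 in the edgeR fit of genotype plus treatment, which sets no minimum fold. Within a single comparison no paired analysis was possible, because each is of 1 library against 1. The fit of genotype plus treatment takes the Al effect with genotype as a block, and so pairs the libraries by genotype. Depth limits genes near 3 reads, and for LUH, LUG and MATE the short covered part of the coding length.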

Other observations

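The families and the tests in this part were chosen after the data were seen. Aquaporins, which are water channels, had a median with Al of -0.53 in Col (5 of 24 fell) and -0.50 in luh-4 (6 of 23 fell), NLM1 at -1.84 (-2.0 to -1.68) and -1.95 (-2.13 to -1.78) and the tonoplast channel gene TIP2;2 at -1.78 (-1.85 to -1.71) and -1.72 (-1.81 to -1.63). Genes described as arabinogalactan proteins, fasciclin-like ones included, had -0.36 and -0.24, with 8 of 34 and 6 of 33 falling. AGP22 fell by 2.34 (-2.52 to -2.16) and 1.60 (-1.74 to -1.46), while AGP1 rose by 1.39 (1.31 to 1.47) and 1.2 (1.12 to 1.27). Genes described as lipid-transfer or glycolipid transfer proteins had -0.22 and -0.25, with 11 and 12 of 53 falling and 2 and 1 rising. Of 59 genes described as class III peroxidases 12 fell and 4 rose in Col, and of 58 in luh-4 7 fell and 3 rose, with medians of -0.05 and -0.01 within the random range. Under Al, 4 of them were higher in luh-4, the root hair genes RHS18 at 1.46 (1.16 to 1.80) and RHS19 at 1.12 (1.04 to 1.2) among them.

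Triterpene genes of the thalianol and marneral clusters stood high in the luh-4 control library. In luh-4 without Al 4 of 5 were higher than in Col, CYP705A5 at 2.08 (1.87 to 2.31), MRN1 at 2.15 (1.41 to 3.98, 42 reads against 7), CYP708A2 at 1.98 (1.08 to 3.69, 34 against 7) and the thalianol synthase gene THAS1 at 1.54 (1.0 to 2.35), and 5 of 5 fell with Al in luh-4 (median -2.13), while in Col 0 of 3 measured passed (median -0.28). Both counts out of 5 use the luh-4 control library, so they are not independent of each other. Comparisons without that library measured 3 members, so the 5 and the 3 are unlike sets. CYP705A5 was lower in luh-4 with Al, at -1.12 (-1.55 to -0.75). Genes described as photosystem, light-harvesting or Rubisco proteins had a median of 0.58 in luh-4 over Col without Al, with 21 of 63 higher and 1 lower (ATCG00520 at -1.49, -3.07 to -0.30). With Al they had -0.33 in Col, below the random range of -0.09 to 0.14, with 7 of 63 lower, and -1.02 in luh-4 (-0.94 with 0 reads set to 3), with 30 of 63 lower. WRKY factors had 0.15 in the Al response of Col, with 6 of 54 rising and 1 falling (ABO3 at -1.22, -2.39 to -0.27), and -0.09 in that of luh-4, within the random range, with 3 of 55 rising and 2 falling. Ribosomal proteins had -0.08 in Col, with 1 of 309 rising, and -0.01 in luh-4, within the range, with 3 of 308 falling.

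Apart from LUH, 3 genes had at least 20 reads in both Col libraries and at most 3 in both luh-4 libraries: AT4G29200 (861 and 748 reads in Col, 1 and 0 in luh-4), QQS (23 and 22, 0 and 0) and MRD1 (190 and 203, 2 and 3). A deletion that reaches the nearest genes with at least 20 reads over both Col libraries together is argued against. Of 6 such neighbours 0 were under 10% of their Col reads in luh-4, with a range from 52.1% for HEI10 beside MRD1 to 119.2%. Such a neighbour need not be the adjacent gene, as with AT3G30380 for QQS (AT3G30720). A deletion that ends among genes with fewer reads would not be seen. HEI10 was lower in luh-4 without Al, at -1.06 (-1.39 to -0.76), and had -0.79 (-1.09 to -0.50) with Al, so a smaller local change beside MRD1 stays open. Linkage to the LUH locus is argued against, since 0 of 3 lie on its chromosome. A background difference between the lines, in sequence or in inherited silencing, may account for these 3 genes, and cannot be told apart from an effect of LUH with 1 mutant line. That all 3 had at most 3 reads in both luh-4 libraries follows from how they were picked, so it does not bear on this.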
